A study of Homo sapiens with 10 samples.

How the data were processed

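The values are gene-level TPM (transcripts per 1000000 transcripts) that the authors deposited in 1 table with a column for each of the 10 libraries. Per the submitters' processing notes, reads were quantified with kallisto on GRCh38 and DESeq2 was also used, and no versions, annotation release or settings are given in the sources used here. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a DNA library kit, and nothing is said of strand, so genes that overlap on opposite strands may not be told apart. Read counts were not analysed here. TPM keeps no depth, so no interval from counting can be given.

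The table has 40320 rows. In 5719 rows the gene symbol occurs more than once (1860 symbols), and these were summed per symbol. A date stood in place of a symbol in 29 rows, which were kept apart and not named. The 36461 genes that resulted were matched by symbol to GENCODE release 29 (GRCh38), where 35319 (96.9%) occur once, and positions are from there. The table also has 6 unnamed columns, all empty. The labels give no replicate numbers, so replicates are numbered in label order, and the numbers pair no libraries. Of the 45 pairs of libraries, 0 held identical values.

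Genes with a mean of at least 1 TPM over the 10 libraries were kept (13158), and log2(TPM + 1) was fitted with limma 3.58.1 (R 4.3.3, eBayes with trend and robust, statmod 1.5.0) in 1 model of the 3 groups, with no covariate. The contrasts were each siRNA against the control, the average of both against the control and siTFEB_2 against siTFEB_1. P-values were adjusted by Benjamini and Hochberg, with a gene called at an adjusted p under 0.05. The design set before the data were examined was a count model, with this limma fit in its place if the table held only TPM, as it did. Fold changes of single genes are differences of means on that scale with their standard errors. TFEB and its relatives were also compared by 2-sided exact permutation tests of TPM.

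The named genes were chosen by a rule fixed before the data were examined, among genes with a mean of at least 3 TPM and a symbol that is not only a clone or locus name: the 8 risen and 8 fallen genes with the largest smaller change of the 2 siRNAs, the 5 risen and 5 fallen with the largest change for each siRNA and between the siRNAs, all with each library on one side, and from each list the 4 genes with the smallest p in the average. By the same rule TFEB, TFE3, MITF and TFEC are named. Some genes that the rule names are not reported here. Gene lists were also written before the data were examined, 32 in all, of which 31 had at least 3 measured genes. They cover the TFEB family, lysosome signalling, hydrolases, lysosomal membrane, proton pump, autophagy, homologous recombination, end joining, excision and mismatch repair, checkpoint, replication, mitosis, p53 response, apoptosis (promoting and inhibiting), interferon, NF-kB, cholesterol, fatty acids, ATF4, unfolded proteins, hypoxia and glycolysis, oxidative phosphorylation, extracellular matrix, ribosomal proteins, RNA interference, double-stranded RNA, mitochondrially encoded genes, histones and markers of luminal epithelial, immune, and fibroblast and endothelial cells. Lists were tested with camera (preset correlation 0.01), with an estimated correlation beside it and with fry as an alternative, and adjusted over the 31 lists within a contrast. A list's medians carry no error of their own. Of 487 calls of named genes, 469 had every siRNA library on the called side of the mean of the group compared. The rule itself required this of genes named for the size of their change, in the comparison that named them. Of 32 calls of lists, 27 had this for the median of the list, and the others were the hydrolase and replication lists with siTFEB_1 (2 of 3 libraries each) and in the average (5 of 6 each) and the hypoxia list in the average (4 of 6).

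Words of 7 bases were counted in the longest 3' UTR of at least 50 bases of each protein-coding gene (GENCODE release 29, 11953 genes). Fold changes were freed of trends with UTR length, GC content and expression, ranked, and compared between genes with and without each word held by at least 50 genes, as a z score. For each TFEB siRNA the 2 words with the lowest z were used, and for the control siRNA the 6 words that passed the threshold over all 16384 words (4.52) with both siRNAs. The words were searched after the gene results were seen. Genes that were not searched are left out wherever genes without the words are tested. The siRNA sequences are not given in the sources used here. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used, and figures were drawn with matplotlib 3.10.9.

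The fit was tested on simulated data with the real means and spreads (13158 genes, 5 runs of 200 changed genes). For the average of both siRNAs, 55.6% of changes of 0.25 on the log2 scale were recovered, 97.2% of 0.5, 100% of 1 and 99.6% of 1.5, with 5.47% false calls. For siTFEB_1 the shares were 35.6%, 94.4%, 99.6% and 99.2% with 5.08% false calls, and for siTFEB_2 40%, 92%, 99.6% and 99.2% with 4.83%. With the replication list shifted by -0.2 in simulated data, camera called it and 0 of the other lists for the average of both siRNAs. Genes were simulated independently, so this cannot show how often camera calls unchanged lists of correlated genes. In the real data the estimated correlation within the replication list was 0.24. Other splits of the real libraries called a median of 5 lists for that average. Each of 5 words planted with a shift of -0.15 in shuffled fold changes of siTFEB_1 came first.

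The alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 TPM, an FDR of 0.01, a minimum fold of 1.2, limma without the robust option, median-of-ratios and upper-quartile factors and quantile normalization of the TPM values, TPM rescaled without mitochondrially encoded genes, rows of one symbol kept apart, fits of only the groups compared, each library left out, the 2 libraries richest in mitochondrial transcripts left out, genes without the words, genes without any of the words past the threshold (lower with either siRNA or higher with both), and controls split 2 and 2, for the genes in common also among genes without the words. Other splits of the same libraries were drawn, all 35 for each siRNA against the control, 100 for the average and for the genes in common, and all 10 between the siRNAs. Unchanged groups were simulated 100 times, with control libraries that were also drawn anew and were shared by both siRNAs.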

Results

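Gene expression was measured by RNA sequencing in 10 libraries of MDA-MB-231, a line of triple-negative breast cancer cells. The cells had been transfected for 48 h with 10 nM of a control siRNA (siCTRL, 4 libraries), of a first siRNA against TFEB (siTFEB_1, 3 libraries) or of a second one (siTFEB_2, 3 libraries). TFEB is a transcription factor best known for switching on genes of lysosomes and autophagy, and the title of the series asks about a part for it in DNA repair and apoptosis apart from the lysosome. The values are TPM, a gene's transcripts per 1000000 transcripts. They keep no trace of the sequencing depth, which is unknown. Between 20208 and 22008 genes had a value above 0 in a library, and 13158 genes with a mean of at least 1 TPM were tested. The labels do not say whether the libraries of a group came from separate cultures, so the replicates may be technical. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. A gene is said to have risen or fallen where its adjusted p from limma was under 0.05, and a list of genes to have passed where its camera adjusted p was.

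TFEB itself lies on chromosome 6 (41683978 to 41736259, minus strand, GRCh38). It stood at 8.02, 9.82, 9.87 and 10.13 TPM in the 4 control libraries, at 3.77, 3.42 and 3.74 TPM in the siTFEB_1 libraries and at 2.47, 2.99 and 2.68 TPM in the siTFEB_2 libraries. Its mean was 9.46 ± 0.97 TPM (SD, n = 4) in the controls, 3.64 ± 0.19 TPM (SD, n = 3) with siTFEB_1 and 2.71 ± 0.26 TPM (SD, n = 3) with siTFEB_2. TFEB was thus 61.5% lower with siTFEB_1 and 71.3% lower with siTFEB_2, and every siRNA library lay below every control library. The 2-sided exact permutation p was 0.0286 for each siRNA, the smallest that 35 splits can give, and limma gave log2 fold changes of -1.17 (SE 0.09, adjusted p = 4.5e-07) and -1.49 (SE 0.09, adjusted p = 1.6e-07). TFEB was 25.5% lower with siTFEB_2 than with siTFEB_1, with an exact p of 0.1, the smallest that groups of 3 and 3 allow. The limma adjusted p of that difference was 0.0159, and the call was lost without siTFEB_2 replicate 1 (0.06345), without the 2 libraries rich in mitochondrial transcripts (0.0536), with quantile normalization (0.0812) and against a minimum fold of 1.2 (0.914).

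The close relatives of TFEB showed no such drop. TFE3 had a mean of 67.4 TPM in the controls, 64.1 TPM with siTFEB_1 and 62.6 TPM with siTFEB_2, and MITF had 9.16, 9.88 and 7.87 TPM in the same order. Neither passed the limma test against the controls with siTFEB_1 or siTFEB_2, with adjusted p = 0.229 and 0.101 for TFE3 and 0.372 and 0.1205 for MITF. Over both siRNAs TFE3 was 5.97% lower (2-sided exact permutation p = 0.0191, limma adjusted p = 0.0874). The fourth member, TFEC, was listed at 0.068 TPM at most in any library and was not tested. With siTFEB_2, MITF was lower than with siTFEB_1 by a log2 difference of -0.30 (SE 0.10, adjusted p = 0.025 by limma, 3 of 3 libraries). That call was lost without siTFEB_1 replicate 2 (0.0612) or 3 (0.08915), without siTFEB_2 replicate 1 (0.0577) or 2 (0.0904), and with no filter on low values (0.0629). It was also lost against a minimum fold of 1.2.

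**Figure D1:**
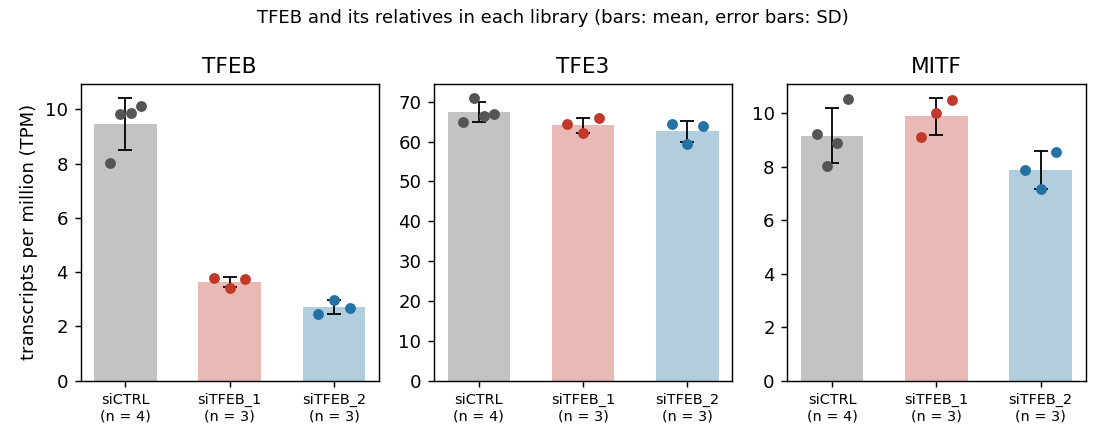
TPM of TFEB, TFE3 and MITF in each library, with points for the 10 libraries, bars for the group means and error bars for the SD. All 6 TFEB siRNA libraries lie at or below 3.77 TPM for TFEB and all 4 control libraries at or above 8.02 TPM.

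The 3 groups separated on the first principal components, which held 47.0% and 23.04% of the variance. Pearson's r across genes was 0.991 to 0.996 between libraries of a group and 0.974 to 0.988 between groups. On the third component, with 8.30% of the variance, libraries of one group lay apart, with siTFEB_1 replicates 1, 2 and 3 at -14.08, 13.68 and 3.41. Replicate 2 of siCTRL lay at -11.36 against 0.93 to 4.89 for the other controls, and siTFEB_2 replicate 3 at 6.61 against -3.22 and -4.15. Mitochondrially encoded transcripts made up 7.11% of the TPM in siCTRL replicate 2, 7.98% in siTFEB_1 replicate 1 and 3.39% to 4.89% in the other 8.

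The comparison of each siRNA with the controls asks which genes change when TFEB is depleted. With both siRNAs, PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis, showed the largest rise in common. It stood at 20.7 ± 1.5 TPM in the controls (SD, n = 4), 77.6 ± 2.6 TPM with siTFEB_1 (SD, n = 3) and 77.8 ± 6.9 TPM with siTFEB_2 (SD, n = 3). The cytokine IL6 and the chemokine CXCL8 fell with both siRNAs, IL6 from 73.5 ± 6.6 TPM (SD, n = 4) to 31.9 ± 2.6 and 37.6 ± 2.8 TPM (SD, n = 3 each). Genes of mitosis, DNA replication and homologous recombination were lower with both siRNAs, while genes of lysosomal hydrolases were slightly higher. The camera adjusted p of the first 3 lists was at most 0.0109 with either siRNA, and that of the hydrolases was 0.048 and 0.00278. None of these calls held with an estimated correlation (adjusted p = 0.676 or more).

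WSB1, a substrate receptor of a ubiquitin ligase, rose with both siRNAs by log2 fold changes of 1.74 and 1.85 (SE 0.11 each). TAPT1 rose by 1.59 and 1.49 (SE 0.09 each) and IGFBPL1, a relative of the insulin-like growth factor binding proteins, by 1.39 and 1.59 (SE 0.07 each). SLC36A1, an amino acid transporter of the lysosomal membrane, rose by 1.55 and 1.29 (SE 0.12 each) on the same scale. BANF1, a protein that binds DNA at the nuclear envelope, rose by 1.38 and 1.16 on that scale. PDCD6, a calcium-binding adaptor, rose from 43.2 to 100.4 and 108.3 TPM. FAM49B, a regulator of the actin cytoskeleton, rose by 1.09 on the log2 scale in the average. Of these 8 genes with the strongest rise in common, 6 carry in their 3' UTR 1 of 6 words of 7 bases that went with higher expression with both siRNAs. Among the searched genes not risen with both, 10.8% carry such a word. After TFEB, the strongest falls in common included that of SGMS2, a sphingomyelin synthase, from 52.1 ± 2.4 TPM (SD, n = 4) to 26.3 ± 4.7 and 25.9 ± 5.1 TPM (SD, n = 3 each). DDAH1, which breaks down methylated arginine, had log2 fold changes of -0.96 and -0.97 (SE 0.05 each). Others were those of the kinase CDKL1 with -0.91 and -1.01, of the actin-binding TWF1 with -0.86 and -1.04, of CXCL8 with -1.30 and -0.84 and of the lipid-binding OSBPL6 with -0.88 and -0.80. Of the 7 genes with the strongest falls in common besides TFEB, 3 carry a word of 7 bases of siTFEB_1 and 5 a word of siTFEB_2, that is, a word that went with lower expression with that siRNA. Among the searched genes not fallen with both, 28.1% carry a siTFEB_1 word and 15.1% a siTFEB_2 word. Of the risen genes above, WSB1, TAPT1 and SLC36A1 carry a siTFEB_1 word, and PTPMT1 and FAM49B a siTFEB_2 word. A word in a single gene thus does not show what moved it. SGMS2, TWF1 and OSBPL6 carry words of both. MCL1, which inhibits apoptosis, rose from 85.3 ± 2.8 TPM (SD, n = 4) to 161 ± 9.8 and 170 ± 5.8 TPM (SD, n = 3 each). MDM2, the main ubiquitin ligase for p53, fell from 40.8 ± 2.5 TPM (SD, n = 4) to 23.1 ± 1.35 and 22.9 ± 4.15 TPM (SD, n = 3 each), and its 3' UTR also holds words of both siRNAs. The largest limma adjusted p among these genes was 0.000287, that of CXCL8 with siTFEB_2. Every siRNA library lay on the called side of the control mean, which the rule required of genes named for the size of their change.

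In all, 2473 genes changed by limma in the same direction with both siRNAs, 1100 risen and 1373 fallen, and 543 changed in opposite directions. Of the 2473 genes, 1450 did not differ between the siRNAs by limma. Independent lists of these sizes would share 1204.5 genes in the same direction, 473.02 risen and 731.46 fallen. Unchanged groups, simulated with 4 shared controls and independent genes, shared 0 genes in each of 100 simulations. With no change in any group, a mean of 0.14 genes was called with siTFEB_1, so that 0 was fixed in advance. It cannot show how many of the 2473 genes the shared controls added. With the controls split 2 and 2 between the siRNAs, 1608 to 1765 genes were shared, where independent lists would give 691.2 to 772.6. The log2 fold changes of the 2 siRNAs had a Pearson's r of 0.383 across genes, which are not independent replicates, against 0.429 (0.371 to 0.497) in the simulations. With split controls r was 0.29 to 0.343. The covariance of the real fold changes was 0.0412 against 0.00558 in the simulations (0.0331 to 0.0383 with split controls), a difference of 0.0356, so the simulated fold changes varied far less than the real ones and the values of r are not on a par. A log2 fold change of at least 1 with both siRNAs was found for 13 risen genes and 1 fallen gene, which was TFEB. With upper-quartile scaling, 57.7% of the shared genes were risen, against 44.5% as the values stand.

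**Figure D2:**
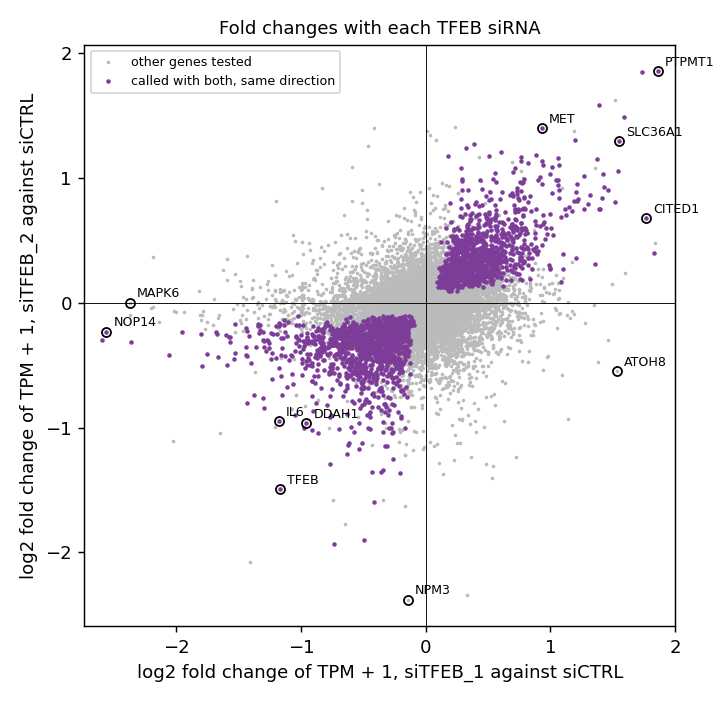
Log2 fold change of each of the 13158 genes tested with siTFEB_1 (horizontal axis) and siTFEB_2 (vertical axis) against the controls, with the 2473 genes called with both in the same direction in purple. The genes with the strongest falls lie along the axes of a single siRNA, and TFEB lies low on both.

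Averaged over both siRNAs, 5994 of 13158 genes changed, 2498 risen and 3496 fallen. That is 41.7% risen, against 54.7% with upper-quartile scaling. Of 48 measured genes of homologous recombination and the Fanconi pathway, 26 fell and 4 rose, with 29 and 4 when adjusted over the list alone and a median log2 fold change of -0.25 (camera adjusted p = 0.00147, and adjusted p = 0.722 with an estimated correlation). RMI1 and RAD54L fell by 0.55 and 0.54 on the log2 scale in the average. Of 22 checkpoint genes, 10 fell and 1 rose, both counts unchanged when adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.02, and adjusted p = 0.722 with an estimated correlation). Among them were CLSPN at -0.39 and RAD17, which holds a siTFEB_2 word, at -0.35. The checkpoint call was lost with quantile normalization (0.0509, median -0.10) and among genes without the words of 7 bases (0.0711), where the median of the 13 members left was -0.17. With siTFEB_2 alone 10 fell and 2 rose, and the checkpoint list did not pass (median -0.14, camera adjusted p = 0.0723). It did so with no filter on low values (0.0102), without siCTRL replicate 3 (0.0496) and with fry (0.00954). The list of end joining (8 fallen and 2 risen of 18, both with and without adjusting over the list alone, camera adjusted p = 0.304) and that of excision and mismatch repair (20 fallen and 7 risen of 39, again in both ways, camera adjusted p = 0.174) did not pass. Excision and mismatch repair passed with no filter on low values (0.01065). Fry, which does not compare a list with other genes, called it (adjusted p = 0.0026) and end joining (0.00389). No test compared these lists with each other, and the end joining and checkpoint lists had the same median of -0.16. Single genes there went both ways, with XRCC4, which joins broken ends with ligase IV, at 0.66 and ERCC5, a nuclease of excision repair, at 0.78, but the helicase ERCC3 at -0.26 and PARP2 at -0.31. XRCC4 and ERCC5 each hold 1 of the 6 words that went with higher expression with both siRNAs.

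DNA replication and mitosis were lower. Of 49 replication genes, 29 fell and 3 rose (30 and 3 adjusted over the list alone, median -0.18, camera adjusted p = 0.00109, and adjusted p = 0.722 with an estimated correlation). They were led by the repressor E2F8 at -0.86, UHRF1 at -0.58, the licensing factor CDC6 at -0.66 and the sliding clamp PCNA at -0.48, of which CDC6 and PCNA hold a siTFEB_1 word. Of 45 genes of mitosis and G2, 37 fell and 1 rose (40 and 1 adjusted over the list alone, median -0.25, camera adjusted p = 5.1e-09, and adjusted p = 0.722 with an estimated correlation). ECT2, which drives cytokinesis, fell from 122.8 ± 9.5 TPM (SD, n = 4) to 44.9 ± 3.4 and 69.9 ± 4.3 TPM (SD, n = 3 each), and its 3' UTR holds words of both siRNAs. The mitotic kinesin KIF23, which holds a siTFEB_2 word, and the securin PTTG1 fell by 0.51 and 0.45 on the log2 scale. All 6 siRNA libraries had a lower median of the mitosis list than the control mean, and 5 of 6 had a lower median of the replication list.

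The lists of apoptosis and of the p53 response did not pass by camera in any comparison, except that of genes that inhibit apoptosis in the average with no filter on low values (0.0327). Fry, which does not compare a list with other genes, called the p53 list with siTFEB_1 (adjusted p = 0.00672), in the average (0.0161) and between the siRNAs (0.044). It called the list of genes that inhibit apoptosis with siTFEB_1 (0.0453) and in the average (0.0251). In the average, 9 of 31 genes that promote apoptosis rose and 12 fell (9 and 12 adjusted over the list alone, camera adjusted p = 0.634). The death ligand TNFSF10 rose by 0.83 on the log2 scale, while its receptor TNFRSF10A fell by 0.77. Of 15 genes that inhibit apoptosis, 2 rose and 7 fell (2 and 7 adjusted over the list alone, camera adjusted p = 0.213), with MCL1 risen, and TRAF1 and BIRC3 fallen by 0.56 and 0.67. TNFRSF10A, TRAF1 and BIRC3 hold a siTFEB_1 word. Of 23 genes of the p53 response, 5 rose and 9 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.665), among the latter MDM2 and the nuclease AEN, which fell by 0.52.

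Lysosomal hydrolases were slightly higher. Of 47 measured, 21 rose and 7 fell in the average (23 and 8 adjusted over the list alone, median 0.09, camera adjusted p = 0.00512, and adjusted p = 0.722 with an estimated correlation). The sialidase NEU1 rose from 79.7 ± 2.2 TPM (SD, n = 4) to 102 ± 1.4 and 100.2 ± 3.8 TPM (SD, n = 3 each). The list median was above the control mean in 5 of 6 siRNA libraries. The lysosomal membrane list (4 risen and 9 fallen of 25 in both ways, camera adjusted p = 0.532), the proton pump list (5 risen and 3 fallen of 17 in both ways, camera adjusted p = 0.252), the autophagy list (10 risen and 9 fallen of 43 in both ways, camera adjusted p = 0.304) and the list of signalling to mTORC1 at the lysosome (5 risen and 2 fallen of 16 in both ways, camera adjusted p = 0.188) did not pass in the average, though fry called the last (0.00389). In the last, the scaffold gene LAMTOR3 rose by 0.42 on the log2 scale and RRAGB, which encodes a GTPase that recruits mTORC1, by 0.32. With siTFEB_1 the lysosomal membrane list had 5 risen and 10 fallen genes (median -0.12, camera adjusted p = 0.45, and 0.0207 by fry). With siTFEB_2 it had 4 risen and 3 fallen (median 0.03, camera adjusted p = 0.767). Of the 3 measured members of the TFEB family, TFEB alone was called in the average (camera adjusted p = 0.207, and 0.000226 by fry).

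Genes of several stress responses moved as well. Of 28 genes of the ATF4 response, 18 fell and 3 rose in the average (18 and 3 adjusted over the list alone, median -0.19, camera adjusted p = 0.00498, and adjusted p = 0.722 with an estimated correlation). Among them ATF3 fell by 0.85, PPP1R15A fell by 0.43 and the tRNA synthetase gene GARS rose by 0.40. The averaged call was lost among the 10 members without any word past the threshold (camera adjusted p = 0.427, median -0.06). With siTFEB_2 alone the ATF4 list did not pass (12 fallen and 4 risen, camera adjusted p = 0.0783). It did so with no filter (0.0156), without siCTRL replicate 1 (0.00724) or siTFEB_2 replicate 2 (0.0444) and with fry (0.0195). Of 40 interferon-stimulated genes, 14 rose and 7 fell (16 and 7 adjusted over the list alone, median 0.13, camera adjusted p = 0.0179, and adjusted p = 0.722 with an estimated correlation). Among them GBP2 rose by 0.77 and IRF7 by 0.43 but IFIT1 fell by 0.44. With siTFEB_1 alone 13 rose and 10 fell, and the interferon list did not pass (median 0.11, camera adjusted p = 0.271). ATF3 holds a siTFEB_2 word and IFIT1 words of both siRNAs. Of 48 ribosomal protein genes 20 rose and 1 fell (23 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 0.000105, and adjusted p = 0.722 with an estimated correlation). That call was lost with quantile normalization (0.26, median 0.03). With siTFEB_2 alone 5 rose and 2 fell, and the ribosomal protein list did not pass (median 0.03, camera adjusted p = 0.105). It did so with no filter (0.0329) and without siTFEB_2 replicate 1 (0.0277) or 3 (0.00491). Of 31 genes of hypoxia and glycolysis 14 rose and 2 fell (16 and 2 adjusted over the list alone, median 0.10, camera adjusted p = 0.00147, and adjusted p = 0.722 with an estimated correlation). The median was higher in 4 of 6 libraries. With siTFEB_1, 3 genes rose and 14 fell (median -0.11), and the list did not pass (camera adjusted p = 0.272). With siTFEB_2, 26 rose and 1 fell (median 0.26), and it passed (5.4e-13). The lists of unfolded proteins (3 risen and 10 fallen of 23 in both ways, camera adjusted p = 0.144) and of inflammation through NF-kB (2 risen and 11 fallen of 22 in both ways, camera adjusted p = 0.0698) did not pass in the average. The former passed with no filter on low values (0.0139), without siCTRL replicate 1 (0.0311) and with fry (0.00499). The latter passed without siCTRL replicate 3 (0.0354), siTFEB_2 replicate 2 (0.0333) or the 2 libraries rich in mitochondrial transcripts (0.0376), with no filter (0.0327), with repeated symbols kept apart (0.034) and with fry (0.00128). Nuclear genes of oxidative phosphorylation were called as a list with a median of 0.07 (9 risen and 2 fallen of 39, 5 and 1 adjusted over the list alone, camera adjusted p = 0.0125, and adjusted p = 0.722 with an estimated correlation). That call ended without siCTRL replicate 2 (0.0894) and without siTFEB_2 replicate 2 (0.0614), without the 2 libraries rich in mitochondrial transcripts (0.0806) and with fry (0.144). Lists of RNA interference (1 risen and 4 fallen of 13 in both ways, camera adjusted p = 0.231), of sensing of double-stranded RNA (4 risen and 3 fallen of 11, 5 and 3 adjusted over the list alone, camera adjusted p = 0.442), of extracellular matrix and mesenchymal genes (13 risen and 7 fallen of 38 in both ways, camera adjusted p = 0.193), of cholesterol synthesis (4 risen and 6 fallen of 25 in both ways, camera adjusted p = 0.747) and of fatty acid synthesis (2 risen and 4 fallen of 12 in both ways, camera adjusted p = 0.634) did not pass in the average. Fry called that of RNA interference (0.0145). The cholesterol list had 12 risen and 6 fallen with siTFEB_1 (camera adjusted p = 0.3135) but 0 risen and 11 fallen with siTFEB_2 (0.0533). With siTFEB_2 it passed with no filter (0.00584), quantile normalization (0.0179), rescaling without mitochondrially encoded genes (0.0317) and fry (0.0248). So it did without siCTRL replicate 2 (0.0193) or 3 (0.0496), siTFEB_1 replicate 2 (0.04795), siTFEB_2 replicate 1 (0.0243) or the 2 libraries rich in mitochondrial transcripts (0.0169). Among genes without the words of 7 bases, the 5 members left of sensing of double-stranded RNA passed (0.0199, median 0.29 against 0.03 over all members, and adjusted p = 0.5035 with an estimated correlation), as they did with siTFEB_1 (0.04205, and 0.637). The 21 members left of extracellular matrix and mesenchymal genes also passed (0.0238, median 0.12 against 0.05, and adjusted p = 0.583 with an estimated correlation).

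**Figure D3:**
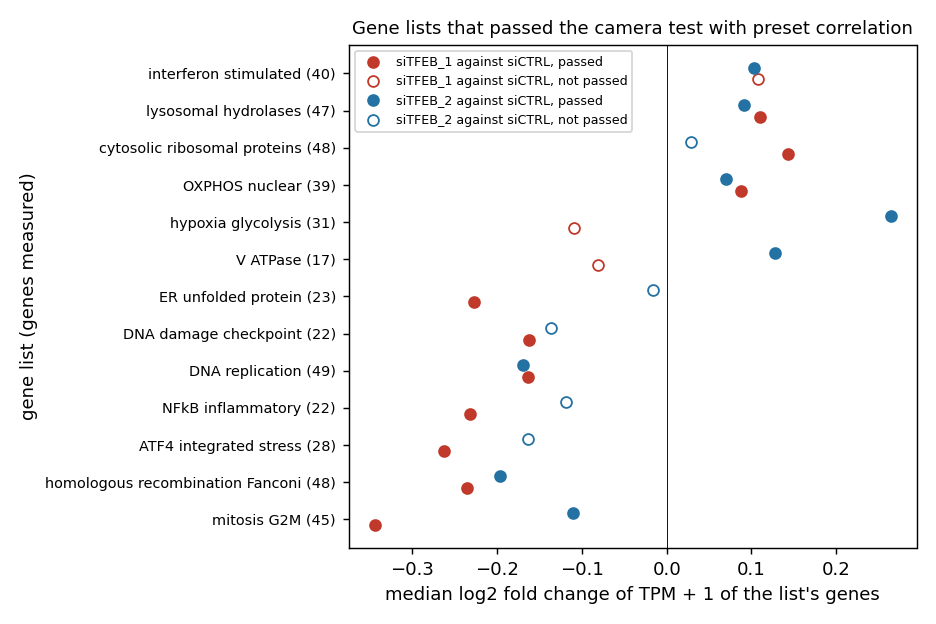
Median log2 fold change of the measured genes of each list that passed the camera test in a comparison with the controls, for siTFEB_1 (red) and siTFEB_2 (blue), filled where the list passed and open where it did not. The mitosis list has the lowest median with siTFEB_1, at -0.34, and the hypoxia and glycolysis list the highest with siTFEB_2, at 0.26.

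With siTFEB_1 the deepest falls were those of MTHFD2, a mitochondrial enzyme of folate metabolism, from 61.8 ± 2.1 TPM (SD, n = 4) to 9.40 ± 0.39 TPM (SD, n = 3), and of NOP14, which helps to build the small ribosomal subunit, from 66.8 ± 1.8 TPM (SD, n = 4) to 10.5 ± 0.52 TPM (SD, n = 3). The kinase MAPK6 fell from 44.2 ± 2.6 TPM (SD, n = 4) to 7.74 ± 0.68 TPM (SD, n = 3), and COMMD8 and the receptor LRP12 fell by 2.37 each on the log2 scale. The 3' UTRs of these 5 genes each hold a word of 7 bases that also lies in the TFEB mRNA and went with lower expression with siTFEB_1. Such a word was held by 28.1% of the searched genes that did not fall 2-fold or more. MTHFD2 also holds a siTFEB_2 word and a word among the 6 that went with higher expression with both siRNAs. Genes of mitosis fell as a list (camera adjusted p = 1.7e-09), and ribosomal protein genes rose slightly (camera adjusted p = 3.0e-06). Neither call held with an estimated correlation (adjusted p = 0.796 each). CITED1, a transcriptional coactivator, rose from 1.47 ± 0.25 TPM (SD, n = 4) to 7.40 ± 0.40 TPM (SD, n = 3), next to PTPMT1, WSB1, TAPT1 and SLC36A1. The limma adjusted p of each of these genes was at most 3.6e-07, in 3 of 3 libraries, as the rule that named them required. By limma CITED1 also rose with siTFEB_2, MTHFD2, NOP14 and LRP12 also fell with it, and all 4 differed between the siRNAs.

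With siTFEB_1, 6893 of 13158 genes changed, or 52.4%, 3057 risen and 3836 fallen, of which 77 and 220 by 2-fold or more. That is 44.4% risen, against 58.3% with upper-quartile scaling. Of the 45 genes of mitosis, 40 fell and 1 rose (the same counts adjusted over the list alone, median -0.34, camera adjusted p = 1.7e-09, and adjusted p = 0.796 with an estimated correlation), with ECT2 at -1.43 and DLGAP5, a spindle protein, at -0.99. Of 48 ribosomal protein genes, whose many pseudogenes make single values uncertain, 30 rose and 1 fell (31 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 3.0e-06, and adjusted p = 0.796 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.12, median 0.07). Genes of the ATF4 response (18 fallen and 3 risen of 28, 19 and 3 adjusted over the list alone, median -0.26, camera adjusted p = 0.00478), of the unfolded protein response of the endoplasmic reticulum (14 fallen and 2 risen of 23 in both ways, median -0.23, camera adjusted p = 0.0182) and of inflammation through NF-kB (13 fallen and 1 risen of 22, 14 and 1 adjusted over the list alone, median -0.23, camera adjusted p = 0.0124) were lower, each with adjusted p = 0.796 with an estimated correlation. Among them were the chaperone cofactor DNAJB9 at -0.84 and the cytokines LIF at -0.72 and IL11 at -0.63, in 3 of 3 libraries each. The 3 calls were lost among the 10, 4 and 5 members without any word past the threshold (camera adjusted p = 0.222, 0.301 and 0.278, medians -0.12, -0.08 and -0.15).

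The replication list (26 fallen and 8 risen, 28 and 9 adjusted over the list alone, camera adjusted p = 0.0109), the homologous recombination list (24 fallen and 5 risen, 26 and 5 adjusted over the list alone, camera adjusted p = 0.00892) and, barely, the checkpoint list (11 fallen and 1 risen in both ways, camera adjusted p = 0.048), the hydrolase list (21 risen and 7 fallen, 22 and 8 adjusted over the list alone, camera adjusted p = 0.048) and the oxidative phosphorylation list (14 risen and 4 fallen, 13 and 4 adjusted over the list alone, camera adjusted p = 0.0489) passed with siTFEB_1, each with adjusted p = 0.796 with an estimated correlation. The checkpoint call was lost without siCTRL replicate 1 (0.0575) or 2 (0.0559), siTFEB_1 replicate 2 (0.0559) or 3 (0.075), or siTFEB_2 replicate 1 (0.0503), and with median-of-ratios (0.05205) or upper-quartile scaling (0.0781), quantile normalization (0.121), a mean of at least 5 TPM (0.09935) or genes without the words of 7 bases (0.233, median -0.12 against -0.16). The hydrolase call was lost without siCTRL replicate 1 (0.0575) or 2 (0.0648), siTFEB_1 replicate 2 (0.0559) or siTFEB_2 replicate 1 (0.0503), without the 2 libraries rich in mitochondrial transcripts (0.052) and with fry (0.0592). That of oxidative phosphorylation was lost without siCTRL replicate 2 (0.2) or 4 (0.0573), siTFEB_1 replicate 1 (0.051) or 2 (0.178), or siTFEB_2 replicate 1 (0.0523), without the 2 libraries rich in mitochondrial transcripts (0.1865), with a pseudocount of 5 (0.051), with median-of-ratios scaling (0.0866), in genes without the words (0.113, median 0.10 against 0.09) and with fry (0.191). Strong single changes in lists that did not pass were those of SQSTM1, an autophagy receptor, from 374 to 212 TPM, of the citrate lyase ACLY from 241 to 88.4 TPM and of the nuclease DICER1 from 26.9 to 9.10 TPM, in 3 of 3 libraries each. ACLY and DICER1 hold a siTFEB_1 word in the 3' UTR, and SQSTM1 does not.

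With siTFEB_2, genes of glycolysis and the hypoxia response rose as a list (camera adjusted p = 5.4e-13, and adjusted p = 0.676 with an estimated correlation). They were led by the glucose transporter SLC2A3, from 24.4 ± 1.7 TPM (SD, n = 4) to 63.7 ± 2.7 TPM (SD, n = 3), and by PFKFB4, a regulator of glycolysis, at a log2 fold change of 0.86. MET, the receptor for hepatocyte growth factor, rose from 22.0 ± 1.5 TPM (SD, n = 4) to 59.7 ± 5.1 TPM (SD, n = 3), next to PTPMT1, WSB1, IGFBPL1 and TAPT1. SLC2A3 and MET each hold 1 of the 6 words that went with higher expression with both siRNAs. The deepest fall was that of NPM3, a histone chaperone, from 61.0 ± 1.7 TPM (SD, n = 4) to 10.9 ± 0.91 TPM (SD, n = 3). USB1, an exonuclease that trims U6 RNA, fell from 80.6 ± 1.5 TPM (SD, n = 4) to 20.4 ± 0.19 TPM (SD, n = 3), and SCML1, the lipid enzyme CDS2 and SCARA3 fell by 1.90, 1.63 and 1.60 on the log2 scale. The 3' UTRs of 4 of these 5 genes hold a word of 7 bases from the TFEB mRNA that went with lower expression with siTFEB_2, CDS2 being the exception. Such a word was held by 15.8% of the searched genes that did not fall 2-fold or more. CDS2 holds a siTFEB_1 word, though it was not called with siTFEB_1, and a word among the 6 that went with higher expression. The limma adjusted p of each of these genes was at most 2.1e-07, in 3 of 3 libraries. The rule required the latter of genes named for the size of their change. By limma MET also rose with siTFEB_1, USB1, SCML1 and SCARA3 also fell with it, and all 4 differed between the siRNAs.

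With siTFEB_2, 4545 genes changed, or 34.5%, 2036 risen and 2509 fallen, of which 36 and 56 by 2-fold or more. That is 44.8% risen, and the risen genes became the larger part with upper-quartile (50.89%) and median-of-ratios scaling (51.5%), quantile normalization (50.59%) and without siTFEB_2 replicate 2 (50.64%). Of 31 genes of hypoxia and glycolysis, 26 rose and 1 fell (27 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 5.4e-13, and adjusted p = 0.676 with an estimated correlation). With siTFEB_1 the same list had 3 risen and 14 fallen genes (4 and 14 adjusted over the list alone) and did not pass (camera adjusted p = 0.272), though it did with no filter on low values (0.0338). The proton pump genes (7 risen and 1 fallen of 17, 8 and 2 adjusted over the list alone, median 0.13, camera adjusted p = 0.0133), the hydrolase genes (18 risen and 4 fallen of 47 in both ways, median 0.09, camera adjusted p = 0.00278) and the interferon-stimulated genes (11 risen and 2 fallen of 40, 12 and 3 adjusted over the list alone, median 0.10, camera adjusted p = 0.0133) were higher, each with adjusted p = 0.676 with an estimated correlation. ATP6V0D1 and ATP6AP1, parts of the proton pump, rose by 0.28 and 0.21. With siTFEB_1 the proton pump list had 3 risen and 5 fallen genes (median -0.08) and did not pass (camera adjusted p = 0.784). The replication list (25 fallen and 3 risen in both ways, camera adjusted p = 9.9e-05) and the homologous recombination list (19 fallen and 2 risen, 20 and 2 adjusted over the list alone, camera adjusted p = 0.00286) were lower, each with adjusted p = 0.676 with an estimated correlation. The mitosis list was lower too (16 fallen and 1 risen, 17 and 1 adjusted over the list alone, median -0.11, camera adjusted p = 0.00174, and adjusted p = 0.812 with an estimated correlation). Oxidative phosphorylation passed (7 risen and 2 fallen, 3 and 2 adjusted over the list alone, camera adjusted p = 0.0363, and adjusted p = 0.882 with an estimated correlation), but not without siCTRL replicate 2 (0.139), siTFEB_2 replicate 2 (0.5112) or the 2 libraries rich in mitochondrial transcripts (0.144). It also failed with a mean of at least 5 TPM (0.052), upper-quartile scaling (0.05455), quantile normalization (0.0834), genes without the words (0.0886, with the same median of 0.07) and fry (0.3065). Single genes of apoptosis that moved with siTFEB_2 were TNFSF10, from 50.5 to 124 TPM, BIRC5, from 106 to 67.8 TPM, and CYCS, from 349 to 136 TPM, the last with many pseudogenes and so uncertain. The 3' UTR of CYCS also holds words of both siRNAs, and that of BIRC5 a siTFEB_1 word.

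The direct comparison of the siRNAs asks which changes differ between them. TFEB was also 25.5% lower with siTFEB_2, so this does not separate effects of the siRNA from those of the TFEB level. Higher with siTFEB_2 than with siTFEB_1 were MAPK6, NOP14, MTHFD2, COMMD8 and the adaptor YWHAH, with log2 differences of 2.38, 2.33, 2.29, 2.27 and 2.16, all of which had fallen with siTFEB_1. Lower were NPM3 at -2.23, the transcription factor ATOH8 at -2.08, the ciliary TMEM216 at -1.94, ID3, which blocks such factors from DNA, at -1.85, and PSG4 at -2.07, a gene with near-identical copies and so uncertain. Of the 5 higher genes 5 carry a siTFEB_1 word, and of the 5 lower genes 1 carries a siTFEB_2 word. ATOH8, TMEM216, PSG4 and ID3 moved in opposite directions with the 2 siRNAs, ID3 from 36.5 ± 2.9 TPM in the controls (SD, n = 4) to 96.7 ± 0.69 TPM with siTFEB_1 and 26.1 ± 1.7 TPM with siTFEB_2 (SD, n = 3 each). The limma adjusted p of these 10 genes was at most 1.8e-07, in 3 of 3 siTFEB_2 libraries, as the rule that named them required.

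In all, 6037 genes, or 45.9%, differed between the siRNAs, 3246 higher and 2791 lower with siTFEB_2, with 204 and 85 by 2-fold or more. That is 53.8% higher, against 42.9% with upper-quartile scaling. Of 31 hypoxia and glycolysis genes, 29 were higher and 0 lower (29 and 1 adjusted over the list alone, median 0.40, camera adjusted p = 3.5e-10). Mitosis genes were higher with siTFEB_2 (31 and 3 of 45, 32 and 4 adjusted over the list alone, median 0.22, camera adjusted p = 0.000105), as were genes of the unfolded protein response (14 and 1 of 23 in both ways, median 0.25, camera adjusted p = 0.00349), while ribosomal protein genes were lower (24 lower and 1 higher of 48, 25 and 1 adjusted over the list alone, median -0.12, camera adjusted p = 0.000163). Each of these 4 lists had adjusted p = 0.983 with an estimated correlation. The words were chosen for their fold changes over all genes, so counts of named genes with a word are not independent evidence. On chromosomes not used to choose it, the word GAAATGC was held by 64.3% (63 of 98) of the genes that fell 2-fold or more with siTFEB_1, against 16% of the others (2-sided Fisher's exact p = 3.8e-26). For siTFEB_2 and GTTCAAC the shares were 66.7% (14 of 21) and 6.55% (2-sided Fisher's exact p = 2.6e-12). These tests were chosen after the results were seen.

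**Figure D4:**
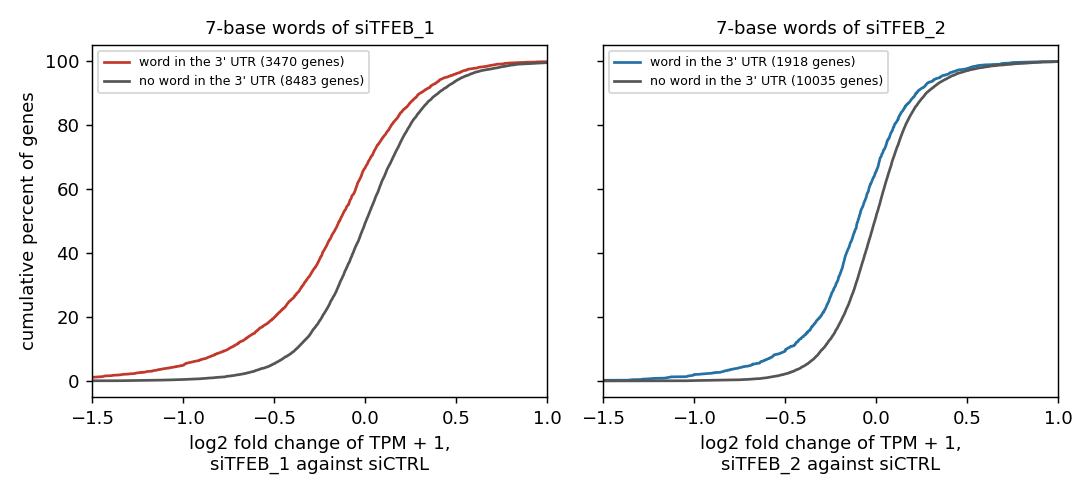
Cumulative percent of genes by log2 fold change, for genes with (coloured) and without (grey) the 2 words of siTFEB_1 (left) or siTFEB_2 (right) in the 3' UTR. In both plots the coloured curve lies to the left of the grey one, that is, towards lower expression, for which the words were chosen.

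The lists of RNA quality and of other cell types passed the camera test in no comparison, except that of mitochondrially encoded genes with siTFEB_1 without siTFEB_1 replicate 2 (0.04055). Of 13 mitochondrially encoded genes, limma called 0 in each comparison, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The list was not called by camera (adjusted p = 0.339 with siTFEB_1, 0.94 with siTFEB_2 and 0.505 in the average) or by fry (0.558, 0.875 and 0.81). Between the siRNAs these were 0.392 and 0.504. Of 11 replication-dependent histone genes, whose near-identical copies make them uncertain, 4 rose and 0 fell in the average by limma (3 and 0 adjusted over the list alone, camera adjusted p = 0.226, and 0.0983 by fry). With siTFEB_1, 4 rose and 0 fell in both ways (median 0.18, camera adjusted p = 0.134, and 0.012 by fry), and between the siRNAs 3 were lower and 0 higher with siTFEB_2 in both ways (median -0.19, camera adjusted p = 0.1545, and 0.0149 by fry). Of 9 luminal epithelial markers, 3 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.665), and of 7 fibroblast and endothelial markers 3 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.269, and 0.0251 by fry). Only 2 of 12 immune markers were measured, so that list was not tested, and its summed TPM was 6.25 in the controls, 9.92 with siTFEB_1 and 13.9 with siTFEB_2.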

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

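No test in this part was chosen after its result was seen. In the 4 control libraries, 155 measures were searched for a library far from the other 3, with the gap to its nearest neighbour given as a share of the whole range. Such a gap was found for 11 measures, where chance gives about 5%, or 7.75 of them.

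In siCTRL replicate 2, mitochondrially encoded genes made up 7.11% of the TPM against 3.45% to 3.89% in the other controls, a gap of 0.878 of the range. The 10 most abundant genes took 8.99% there against 7.47% to 7.51%, a gap of 0.973. MT-CO1 stood at 6407 TPM against 3241 to 3364 TPM (0.961), and MT-ND6 at 1828 TPM against 829 to 917 TPM (0.911). In the same library CDKL1 was high, at 13.9 TPM against 12.04 to 12.21 TPM (0.909), PARP2 was high, at 53.5 TPM against 49.7 to 50.2 TPM (0.862), and NEU1 and RAD23B were low, at 76.4 TPM against 80.5 to 81.0 TPM (0.892) and at 132.0 TPM against 139.9 to 140.8 TPM (0.898).

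In siCTRL replicate 1, TFEB was low, at 8.02 TPM against 9.82 to 10.13 TPM (0.855), which is above every siRNA library, and LAMTOR3 was high, at 34.0 TPM against 30.8 to 31.0 TPM (0.941). In siCTRL replicate 4, IL6 was high, at 83.5 TPM against 69.78 to 70.96 TPM (0.914).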

How the results depend on the processing

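Alternatives that used median-of-ratios, upper-quartile or quantile scaling of the TPM values, rescaling without mitochondrially encoded genes, a mean of at least 5 TPM, a minimum fold of 1.2, no robust option, repeated symbols kept apart, genes without seed words or without any word past the threshold, or leaving out the 2 libraries rich in mitochondrial RNA were chosen after seeing the data. The planned count tests, voom, their scaling factors, filters on counts and minimum-fold test were not run, since the values are TPM. No called result changed its direction. Of 14680 repeats for the named genes (598 results, 26 settings), 14110 kept their direction and side of the threshold, 484 lost the call and 86 gained it. Of 2289 repeats of the list tests (93 results, 25 settings), 2128 kept both, 88 lost the call and 73 gained it. TFEB was called with each siRNA in all 24 settings that include it.

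At an FDR of 0.01, 2777 genes were called with siTFEB_2 and 1460 with both in the same direction. Against a minimum fold of 1.2 the counts were 2082 with siTFEB_1, 704 with siTFEB_2, 1119 in the average, 282 with both and 1695 between the siRNAs, by construction a stricter test. With only the groups compared in the fit, the average gave 2928 genes, since the 6 siRNA libraries then form 1 group whose spread includes the difference between siRNAs. With the controls split, the genes in common numbered 1618, 1614 and 1608 where siTFEB_1 was given siCTRL replicates 1 and 2, 1 and 3, and 1 and 4, with fewer controls for each siRNA.

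The correlation of the fold changes of the siRNAs across genes, 0.383, was 0.363 with a pseudocount of 0.1, 0.399 with 5, 0.398 (0.3979) with a mean of at least 5 TPM, 0.3982 without the 2 libraries rich in mitochondrial RNA, 0.417 in genes without seed words, and 0.416 (0.4163) in those without any word past the threshold. It was 0.365 to 0.406 with 1 library left out. With split controls it was 0.336, 0.311, 0.29 (0.2901), 0.343, 0.328 and 0.2898. The cause of these moves was not tested.

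With no filter on low values, 17 lists were called with siTFEB_2 in place of 8, and 10 between the siRNAs in place of 4, and the cause was not tested. Between the siRNAs, 4 to 7 lists were called with 1 library left out, the most without siTFEB_1 replicate 2. Camera with an estimated correlation called 0 lists with siTFEB_1, 0 with siTFEB_2, 0 in the average and 0 between the siRNAs, with 0, 1, 0 and 1 lists at an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 18, 15, 19 and 19. In the 2920 genes without any word past the threshold, 1518 were called with siTFEB_1, 1063 with siTFEB_2, 1337 in the average, 579 with both in the same direction and 1283 between the siRNAs, since fewer genes were tested. There 3, 4, 3 and 2 lists were called with siTFEB_1, with siTFEB_2, in the average and between the siRNAs, with fewer members each. Some calls were lost with a median as far from 0 as over all members, those of the hydrolases (adjusted p = 0.262 with siTFEB_1, 0.0659 with siTFEB_2 and 0.0925 in the average, medians 0.16, 0.12 and 0.09 against 0.11, 0.09 and 0.09), interferon (0.053 with siTFEB_2 and 0.128 in the average, medians 0.10 and 0.14 against 0.10 and 0.13) and oxidative phosphorylation with siTFEB_1 and in the average (0.301 and 0.325, medians 0.11 and 0.07 against 0.09 and 0.07). Others moved slightly towards 0, those of ribosomal proteins (0.0656 with siTFEB_1 and 0.171 in the average, medians 0.13 and 0.08 against 0.14 and 0.09), hypoxia in the average (0.0925, 0.09 against 0.10) and, with siTFEB_2, the proton pump (0.1685, 0.10 against 0.13) and oxidative phosphorylation (0.577, 0.05 against 0.07). Medians much nearer 0 were those of the ATF4 response (0.222 with siTFEB_1 and 0.427 in the average, -0.12 and -0.06 against -0.26 and -0.19), the checkpoint (0.466 and 0.325, -0.10 and -0.08 against -0.16 each) and, with siTFEB_1, NF-kB (0.278, -0.15 against -0.23) and unfolded proteins (0.301, -0.08 against -0.23). The depth of the libraries is unknown, so what it limits cannot be given.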

Other observations

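The tests of knockdown depth, of the shares of genes with a word, of the words on other chromosomes, of genes without the words (also with split controls) or without any word past the threshold, and of single lists in other splits were chosen after the results were seen. Single genes of matrix and mesenchymal cells moved. Their list did not pass over all members (camera adjusted p = 0.0562 with siTFEB_2 and 0.193 in the average). With siTFEB_2 it passed without siCTRL replicate 3 (0.0496) or 4 (0.0334), siTFEB_1 replicate 1 (0.046) or 2 (0.04795) or siTFEB_2 replicate 1 (0.0487) or 2 (0.0416), and with no filter on low values (0.00956). Among the 21 of 38 members searched and found without the words it passed with siTFEB_2 (0.00966, median 0.19 against 0.07 over all members) and in the average (0.0238, median 0.12 against 0.05), with adjusted p = 0.547 and 0.583 with an estimated correlation. The other members hold a word or, as CCN2 and CCN1, were not searched. Among the 7 members without any word past the threshold it did not (0.717 and 0.4265, medians 0.02 and -0.02). CCN2 and CCN1, targets of YAP signalling, fell with both siRNAs, CCN2 from 201 to 94.1 and 150 TPM and CCN1 from 779 to 522 and 546 TPM. TGFBI rose from 53.2 to 69.3 and 88.5 TPM. The limma adjusted p of these 3 genes was at most 2.1e-05, in 3 of 3 libraries with each siRNA. TIMP3, an inhibitor of matrix proteases, stood at 216 TPM in the controls, 220 TPM with siTFEB_1 and 410.1 TPM with siTFEB_2 (limma adjusted p = 2.1e-08 between the siRNAs). STARD4, a sterol carrier, stood at 59.7 TPM in the controls, 25.9 TPM with siTFEB_1 and 53.4 TPM with siTFEB_2 (limma adjusted p = 5.7e-08 between the siRNAs), and its 3' UTR holds a siTFEB_1 word.

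Many genes fell strongly with a single siRNA, most of them with siTFEB_1. Among genes called with both in one direction, the median size of change with siTFEB_2 was 0.8052 of that with siTFEB_1 (0.77 to 0.89 with 1 library left out). A deeper knockdown of TFEB alone would make it larger. Effects of a single siRNA may enter these genes too, so the ratio cannot decide on depth. Of genes fallen with both, 36.1% hold a siTFEB_1 word and 23.5% a siTFEB_2 word, against 28.1% and 15.1% of the rest. Of all words, GAAATGC went with the lowest expression with siTFEB_1 (z = -16.825, against -0.885 with siTFEB_2) and GTTCAAC with siTFEB_2 (z = -15.429, against -0.62 with siTFEB_1), and both lie in the coding part of the TFEB mRNA (chromosome 6, 41689745 to 41689751 and 41687147 to 41687153, GRCh38), which holds 19.9% of all words. Many of these falls may therefore be direct effects of each siRNA on transcripts that match its seed, since on chromosomes not used to choose the word it was held by 64.3% (63 of 98) and 66.7% (14 of 21) of the genes that fell 2-fold or more, against 16% and 6.55% of the rest. A response to the loss of TFEB stays open, since among the 7042 genes without the words 830 to 909 changed alike with both siRNAs when the controls were split 2 and 2 between them, where independent lists would give 351.7 to 403.2, though all 4 controls received the same siRNA.

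The genes that rose with both siRNAs share their control libraries, in which seed matches of the control siRNA would lower transcripts. GACAGTA went with the highest expression in the average (z = 8.798), and with 5 others it passed the threshold with both siRNAs. The 5 others all hold GACGTA. The word chosen on the odd chromosomes, GACGTAA (z = 7.316), ranked 74 on the others (z = 2.663). The words of the TFEB siRNAs chosen in this way ranked 1 there. Of the 6 words, GACAGTA (z = 5.02 and 7.46) and TGACGTA (6.25 and 5.195) passed the threshold in both parts. On the chromosomes that are not odd, AGACGTA (3.03), GACGTAC (3.98) and GACGTAT (4.40) did not pass, nor did GACGTAA. The 6 words were chosen on all chromosomes, so their values in the parts are no independent test. Some rises, such as those of PTPMT1 and SLC36A1, may reflect the control siRNA rather than TFEB. This stays open, since no library without siRNA is among those analysed here.

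For the lists of mitosis, DNA replication and homologous recombination, leaving out the members with 1 of the 2 words of each siRNA or a control word, and any not searched, kept at least 0.9068 of the median fall in the average. Each list was still called by camera with a preset correlation, but with an estimated correlation none was called even with all members (adjusted p = 0.722). More words passed the threshold, 15 for lower expression with siTFEB_1 and 11 with siTFEB_2. Among the 2920 genes with none of these or of the 6 control words, 18 mitosis, 15 replication and 8 homologous recombination genes were left, with medians of -0.22, -0.18 and -0.33 in the average (camera adjusted p = 1.6e-07, 0.00423 and 0.00162, and 0.357, 0.456 and 0.357 with an estimated correlation). With siTFEB_2 alone the replication median moved from -0.17 over all members to -0.11 (camera adjusted p = 0.00939, and 0.486 with an estimated correlation). The medians of mitosis and homologous recombination moved from -0.11 to -0.10 and from -0.20 to -0.30. Seed matches of the members to these words thus do not account for the lower medians in the average, while indirect effects of the siRNAs stay open.

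Other splits of the same libraries bear on the counts. For genes, the real groups gave the most calls with siTFEB_1 (6893 against at most 2178 in the other splits, 1 of 35 as large) and with siTFEB_2 (4545 against 3, 1 of 35). So they did in the average (5994 against 2620, 1 of 100) and for genes in common (2473 against 1158, 1 of 100). Each share is under 0.05 and the smallest that these splits can give. If the replicates are technical, such splits cannot exclude a chance difference between the cultures of the groups. Between the siRNAs the 10 splits are too few for a share under 0.05, with 6037 genes against at most 2 (1 of 10 as large) and 4 lists against at most 9 (9 of 10). For the number of lists called, chance cannot be excluded with siTFEB_1 (10 against 10, 2 of 35), with siTFEB_2 (8 against 13, 14 of 35) or in the average (10 against 12, 6 of 100). Of 93 tests of single lists in these 3 comparisons, 2 had a share of splits under 0.05, with no adjustment for their number. These were hypoxia with siTFEB_2 (1 of 35 splits in an exact permutation of the libraries, camera p = 1.7e-14 against 2.0e-14 in the nearest other split) and mitosis in the average (3 of 100). With siTFEB_1 the ribosomal protein list had 13 of 35 and the oxidative phosphorylation list 18 of 35.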
